A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

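The deposited values came in a pair of tables. The count table holds raw read counts per feature, which the authors made by assigning reads to the features of genome build R64 with featureCounts of the Subread package, per the submitters' processing notes. The TPM table holds transcripts scaled for feature length within each library, computed by the authors from those counts and deposited beside them. The aligner, the software versions and the settings for strand and for reads that map to several places are not given in the sources used here, so counts of overlapping genes and of near-identical copies are uncertain. Deposited TPM matched the counts divided by a fixed length to within 7.72e-05% for values of at least 100 counts, and TPM sums ran from 999791 to 999870. Both tables held 7032 features, none without a name, and 24 columns, one for each library. Of the features 5953 were matched to the R64 annotation by locus tag and 122 by symbol, and 957 were left without a position. Counts were 0 in every library for 150 features.

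Each library was put in the size group of the nearest multiple of 5 fL, or the upper one where it lay midway, so that the library of 67.5 fL fell in the 70 fL group. This gave 8 groups of 3, and replicates within a group were numbered in the order of the sample records. The labels say that the replicates are biological and that similar cultures were pooled, and no number links libraries of different sizes. No pair of replicates was a copy of another, since the chi-square per degree of freedom between replicates ran from 9.38 to 268.

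Genes were tested with edgeR (4.0.16, R 4.3.3) by the quasi-likelihood F test with robust estimation, on the counts of all 24 libraries, with TMM factors, the filterByExpr filter by group and 1 coefficient per size. This left 6402 genes, with a common biological coefficient of variation of 0.179. TMM factors were 1.16 to 1.17 at 40 fL and 0.929 to 1.04 at the other sizes. One test covered the 8 sizes together, and contrasts in the same fit compared 75 with 40 fL, 50 with 40 fL, 60 with 50 fL and 75 with 60 fL. These share libraries, so overlaps between them were not counted. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are given with an approximate standard error (SE), the absolute log2 change divided by the square root of the F statistic. Changes are relative to the TMM scaling, under which the median of all genes stood at 0.05 from 40 to 50 fL and at -0.01 from 40 to 75 fL, where library totals alone put it at -0.19 and -0.28.

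Gene lists were tested with camera of limma (3.58.1) on log2 CPM with a prior count of 2, the same design and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 34 lists, each of which had at least 5 tested members. They cover G1/S regulators and budding, DNA replication, histones, spindle and kinetochore, the CLB2 cluster, Mcm1 targets and the MCM complex, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, ergosterol, fatty acids, phospholipids, sphingolipids, storage lipids, cell wall, glycolysis, trehalose and glycogen, the TCA cycle, oxidative phosphorylation, mitochondrially encoded genes, environmental stress, chaperones, amino acid synthesis, sulfur, purine and one-carbon, phosphate, iron, hexose transporters, glucose-repressed genes, the proteasome, small nucleolar RNAs, and as checks of cell type haploid-specific and meiosis genes. One of the 34 lists is not reported here, though the counts of called lists include it. In the small nucleolar list 3 members are not of that class in the annotation. Each list was also tested with an estimated correlation and with fry. Some genes stand in more than 1 list.

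The tests, lists, contrasts and alternatives, and the rule for naming genes, were chosen before the data were examined, except where the text says otherwise. By that rule the text could name the 20 called genes with the largest range over the sizes, the 10 largest rises and 10 largest falls from 40 to 75 fL, the 5 largest of each in the other contrasts, 42 landmark genes of the cell cycle and lipid synthesis, and up to 4 members per list with the smallest adjusted p. The ranges, rises and falls were limited to genes with a mean of at least 10 CPM and a symbol other than the systematic name, and the rises and falls to genes whose libraries did not overlap between groups. List members named because a count was 5 or fewer were chosen after their values were seen. Shares of RNA classes were compared by two-sided exact permutation tests. Small nuclear and other small structured RNAs were split off as a class of their own after the annotation was read, which made 6 classes. The share of 31-base words of a gene that are repeated in the genome measured how far copies could share reads. It includes words repeated within the gene itself.

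Alternatives were RLE and upper quartile factors, library totals, DESeq2 (1.42.0), limma-voom, no filter, a filter of 1 CPM in 3 libraries, limma on log2 of the deposited TPM plus 1 or plus 0.1, removal of structural and mitochondrially encoded RNA, a fit of the 6 libraries compared, a fold threshold of 1.2, a spline of measured size with 3 degrees of freedom, and each library left out in turn. Where leaving a library out left 2 in a group, the fit pooled the spread over all groups. In a simulation of 75 against 40 fL with 50 genes changed at each fold, edgeR recovered 25 at 1.5-fold, 44 at 2-fold, 50 at 4-fold and 50 at 8-fold, none in the wrong direction, and called 9 of 6151 unchanged genes. With no change simulated between 50 and 60 fL it called 0 genes. A list shifted 1.5-fold was called by all 3 list tests and no unchanged list was. Simulated genes varied independently, and no simulated pool deviated as a whole. The simulation thus does not show how the gene or list tests behave where genes vary together or a pool deviates.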

Results

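RNA levels were measured across a series of cell sizes in diploid budding yeast. The strain, BY4743, is a laboratory wild type, grown in rich medium (YPD) at 30 °C. Centrifugal elutriation, which sorts cells by size, gave small G1 cells that were then cultured until they reached the desired size, quenched and frozen. Elutriated cultures of similar size were pooled, and each pool gave 1 library of rRNA-depleted total RNA, so a replicate here is a biological pool. The 24 libraries were labelled with mean cell sizes from 39.1 to 75.9 fL and fell into 8 groups of 3, named by the nearest multiple of 5 fL from 40 to 75 fL. The library labelled 67.5 fL, midway between 65 and 70, was put in the 70 fL group as its replicate 1. Total counts per library ran from 16103753 to 24408547 over 7032 features. The question the labels give is how RNA levels change as cells of one strain grow larger through a division cycle. Values are CPM, counts scaled to a common library total and so a share of each library and not an amount per cell, given as mean ± SD (n = 3 libraries). Positions are from the genome build R64. Protein, metabolite and lipid measurements of the same pools were not analysed here.

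The genes that BY4743 lacks were checked first. URA3 and LEU2, which are deleted in this strain, had 0 counts in 24 of 24 libraries. This allows up to 0.186 CPM at the lowest depth (3 counts over the total without a TMM factor, covering counting error only). HIS3, which is only partly deleted in this background, had 324 to 983 counts per library. Among RNA classes, rRNA and its spacers took 0.270% ± 0.00871 of counts at 40 fL and 0.359% ± 0.0294 at 75 fL, and tRNA took 0.0151% ± 0.00231 and 0.00712% ± 0.000641 (SD, n = 3). Small nuclear and other small structured RNAs took 3.41% ± 0.0720 and 3.80% ± 0.0753, small nucleolar RNAs 2.22% ± 0.208 and 2.18% ± 0.0834, and mitochondrially encoded RNAs 0.794% ± 0.0748 and 0.698% ± 0.175. All other features together took 93.3% ± 0.253 and 92.9% ± 0.264 of counts. With deposited TPM that difference turned, to 86.5% ± 0.659 and 87.8% ± 0.374, and small nucleolar RNAs took 6.68% ± 0.689 and 5.32% ± 0.247. None of the 6 class differences between 75 and 40 fL passed a two-sided exact permutation test, in which 3 libraries against 3 cannot give a p under 0.1. The adjusted p was 0.2 for rRNA, tRNA and small nuclear RNA, whose unadjusted p was 0.1, and 0.45 for all other features, 0.6 for mitochondrially encoded RNA and 0.9 for small nucleolar RNA.

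Most of the transcriptome differed among the size groups. Cells were cultured until they reached each size, so size cannot be told apart here from time in culture or from the cultures pooled. CLB1, a mitotic cyclin gene (YGR108W, chromosome VII, 703636 to 705051), had the largest range between group means among the genes that could be named, 7.38 on the log2 scale (edgeR adjusted p = 6.35e-06 over the 8 sizes). The thiamine synthesis gene THI4 (YGR144W, chromosome VII, 780399 to 781379) ranged over 6.93 and the cell wall mannoprotein gene TIR1 (YER011W, chromosome V, 175248 to 176012) over 6.91. THI5, another thiamine synthesis gene, ranged over 7.16, but 91.8% of its 31-base words are repeated in the genome. In the edgeR test over the 8 sizes 5096 of 6402 genes passed, or 79.6%. By the group with the highest mean, 1497 of these genes were highest at 40 fL, 599 at 45, 852 at 50, 150 at 55, 617 at 60, 280 at 65, 517 at 70 and 584 at 75 fL. By the lowest mean, 1830 were lowest at 40 fL and 1135 at 60 fL. The first component of the log2 CPM of all tested genes held 54.1% of the variance and the second 16.6%.

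The G1/S, DNA replication and histone lists had their highest mean at 60 fL and the CLB2 cluster at 75 fL, and all of them were lowest at 40 fL. The list of G1/S regulators and budding genes stood 1.94 ± 0.58 above its 40 fL mean at 45 fL and was highest at 60 fL, 3.57 ± 0.04 (log2, SD, n = 3). DNA replication genes were also highest at 60 fL, at 2.26 ± 0.06, and stood at 1.45 ± 0.22 at 75 fL. Histone genes stood at 1.82 ± 0.95 at 50 fL and 3.27 ± 0.58 at 55 fL, and then stayed between 3.23 and 3.40 up to 75 fL. The CLB2 cluster, a group of mitotic genes, stood at 2.29 ± 0.09 at 60 fL and 3.25 ± 0.01 at 65 fL. It changed little after that, with 3.21 at 70 fL and 3.25 at 75 fL. Ribosome biogenesis genes were lowest at 60 fL, at -1.64 ± 0.08, while ribosomal protein genes stood at 0.86 there and at 1.02 ± 0.07 at 75 fL. These list means are descriptive, and the tests between sizes follow.

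**Figure D1:**
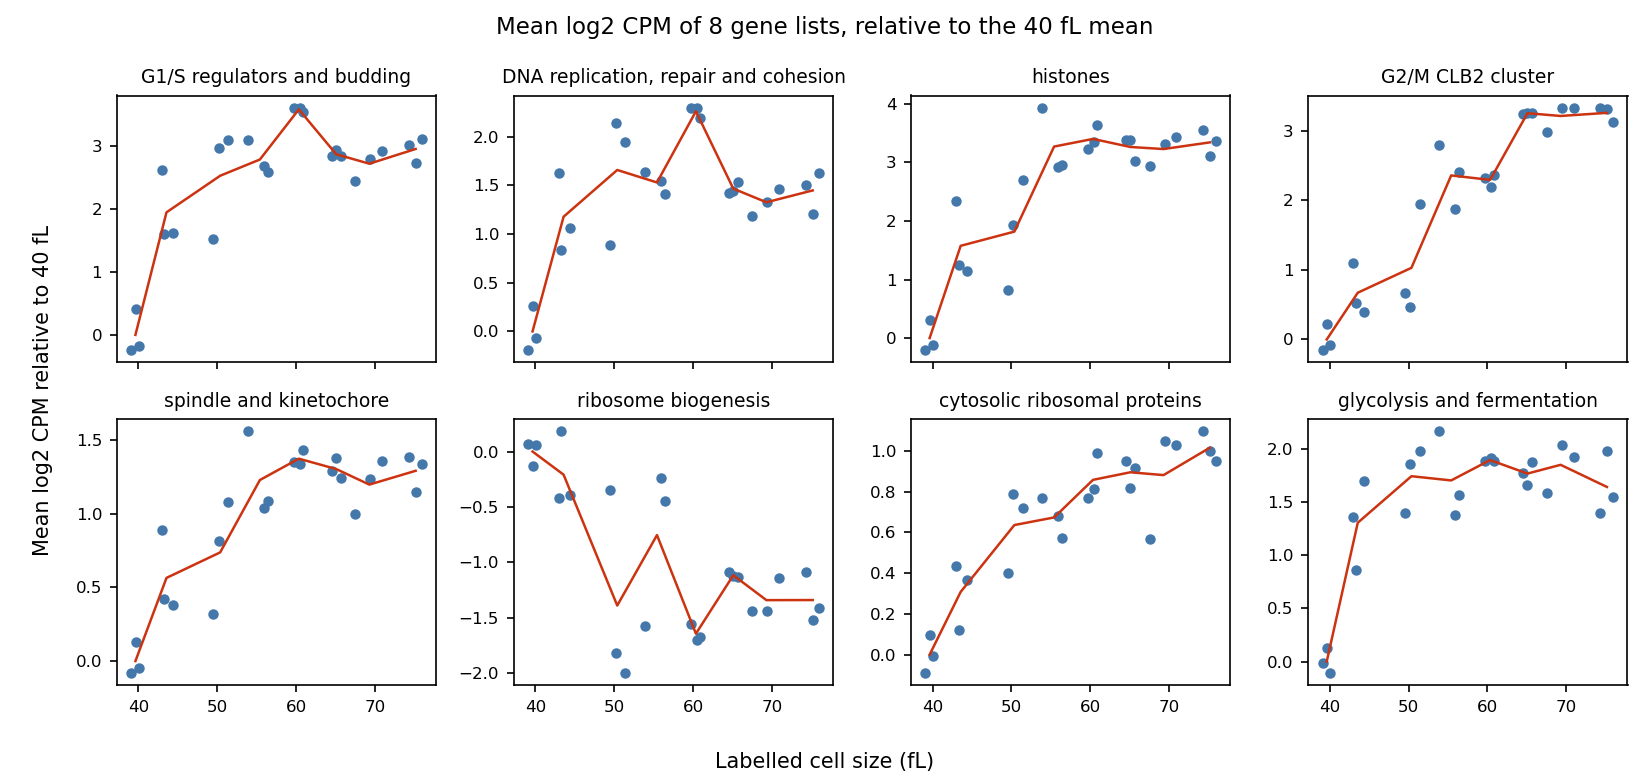
Mean log2 CPM of 8 gene lists relative to their 40 fL mean (y axis, log2) against labelled cell size in fL (x axis), where blue points are single libraries and red lines join the means of the 8 size groups. G1/S and DNA replication genes are highest at 60 fL (3.57 and 2.26), the CLB2 cluster reaches 3.25 at 65 fL, and ribosome biogenesis is lowest at 60 fL (-1.64).

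Libraries of the same size were not equally close. In 5 of the 24 libraries the mean distance to both others of their size was at least 1.4 times the distance between those others. These were 40 fL replicate 1 (ratio 1.67), 45 fL replicate 3 (1.45), 50 fL replicate 2 (1.95), 55 fL replicate 2 (1.72) and 70 fL replicate 1 (1.84). For ribosome biogenesis, 50 fL replicate 2 stood at -0.35 where its mates stood at -2.00 and -1.82, and for G1/S genes it stood at 1.52 where they stood at 3.10 and 2.95. In 55 fL replicate 2 ribosome biogenesis stood at -1.57 and its mates at -0.24 and -0.45, and in 70 fL replicate 1 chaperone genes stood at 1.33 and its mates at 0.71 and 0.69. For environmental stress genes, 45 fL replicate 3 stood at -0.21 and its mates at 1.76 and 0.76, and 40 fL replicate 1 at 0.63 and its mates at -0.41 and -0.22. The tests that follow use all 24 libraries, and changes without single libraries are given beside them.

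Between the smallest and the largest cells, a mitotic cyclin had the largest rise among the genes that could be named, and CIT2, GAP1 and ARG1 were among those that fell. CLB1 rose from 3.29 ± 1.68 CPM at 40 fL to 488 ± 60.1 at 75 fL (n = 3 each), by 7.20 ± 0.78 on the log2 scale (SE, edgeR adjusted p = 1.46e-06). CLB2, its paralog (YPR119W, chromosome XVI, 771653 to 773128), rose from 6.18 ± 1.38 to 217 ± 21.2 CPM, and CHS2, the chitin synthase of the division septum (YBR038W, chromosome II, 311898 to 314789), from 2.65 ± 0.828 to 187 ± 22.5 CPM. CIT2, the peroxisomal citrate synthase (YCR005C, chromosome III, 120946 to 122328), fell from 350 ± 68.9 to 36.9 ± 2.21 CPM. GAP1, the general amino acid permease (YKR039W, chromosome XI, 515063 to 516871), fell from 530 ± 63.8 to 63.7 ± 17.3 CPM, and ARG1, an enzyme of arginine synthesis (YOL058W, chromosome XV, 219211 to 220473), from 447 ± 40.3 to 22.3 ± 5.44 CPM. The largest fall was that of RCK1, a protein kinase gene (YGL158W, chromosome VII, 207033 to 208571), by 4.40 ± 0.70 on the log2 scale. Other large rises were SFG1 (6.00 ± 0.74), the histone H2A gene HTA2 (5.59 ± 0.67), SIM1 (5.41 ± 0.56), SPS4 (5.38 ± 0.68), SRL1 (5.18 ± 0.58), AIM20 (5.11 ± 0.46) and TIR1 (4.91 ± 0.69). Other large falls were PRM7 (-3.71 ± 0.74), the carbonic anhydrase gene NCE103 (-3.50 ± 0.63), the RNA helicase gene DBP2 (-3.41 ± 0.71), MPC3 (-3.30 ± 0.77), TIP1 (-3.26 ± 0.53) and the kinase gene SPS1 (-3.05 ± 0.53). These 20 genes were taken from those whose libraries did not overlap between the groups. In edgeR 3919 of 6402 genes passed, 1985 up and 1934 down, and 676 and 681 of them changed at least 2-fold. With library totals in place of TMM factors the split was 1221 up and 2941 down, where the median of all genes stood at -0.28 and not at -0.01, and with deposited TPM (plus 1, limma) it was 932 up and 3518 down.

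Regulators of the G1/S transition went different ways between 40 and 75 fL. CLN3, the most upstream G1 cyclin gene (YAL040C, chromosome I, 65778 to 67520), fell from 172 ± 9.69 to 110 ± 7.50 CPM (log2 change -0.65 ± 0.17, edgeR adjusted p = 0.00321). The G1 cyclin genes that act after it rose, CLN1 (YMR199W, chromosome XIII, 662644 to 664284) by 4.58 ± 0.48 and CLN2 by 4.09 ± 0.49. WHI5, a repressor of the transition (YOR083W, chromosome XV, 479533 to 480420), went from 9.75 ± 1.04 to 17.3 ± 1.22 CPM, a rise of 0.83 ± 0.21 that did not pass with deposited TPM. SWI4, the DNA-binding subunit of the factor that WHI5 represses, rose by 1.79 ± 0.30, and the CDK gene CDC28 by 0.85 ± 0.09. SIC1, an inhibitor of that kinase, rose from 45.4 ± 0.341 to 104 ± 13.0 CPM, the mitotic kinase gene CDC5 by 4.09 ± 0.38, and the transcription factor gene SWI5 by 4.15 ± 0.52. BCK2, another activator of the transition, had a log2 difference of -0.13 ± 0.07 and did not pass.

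**Figure D2:**
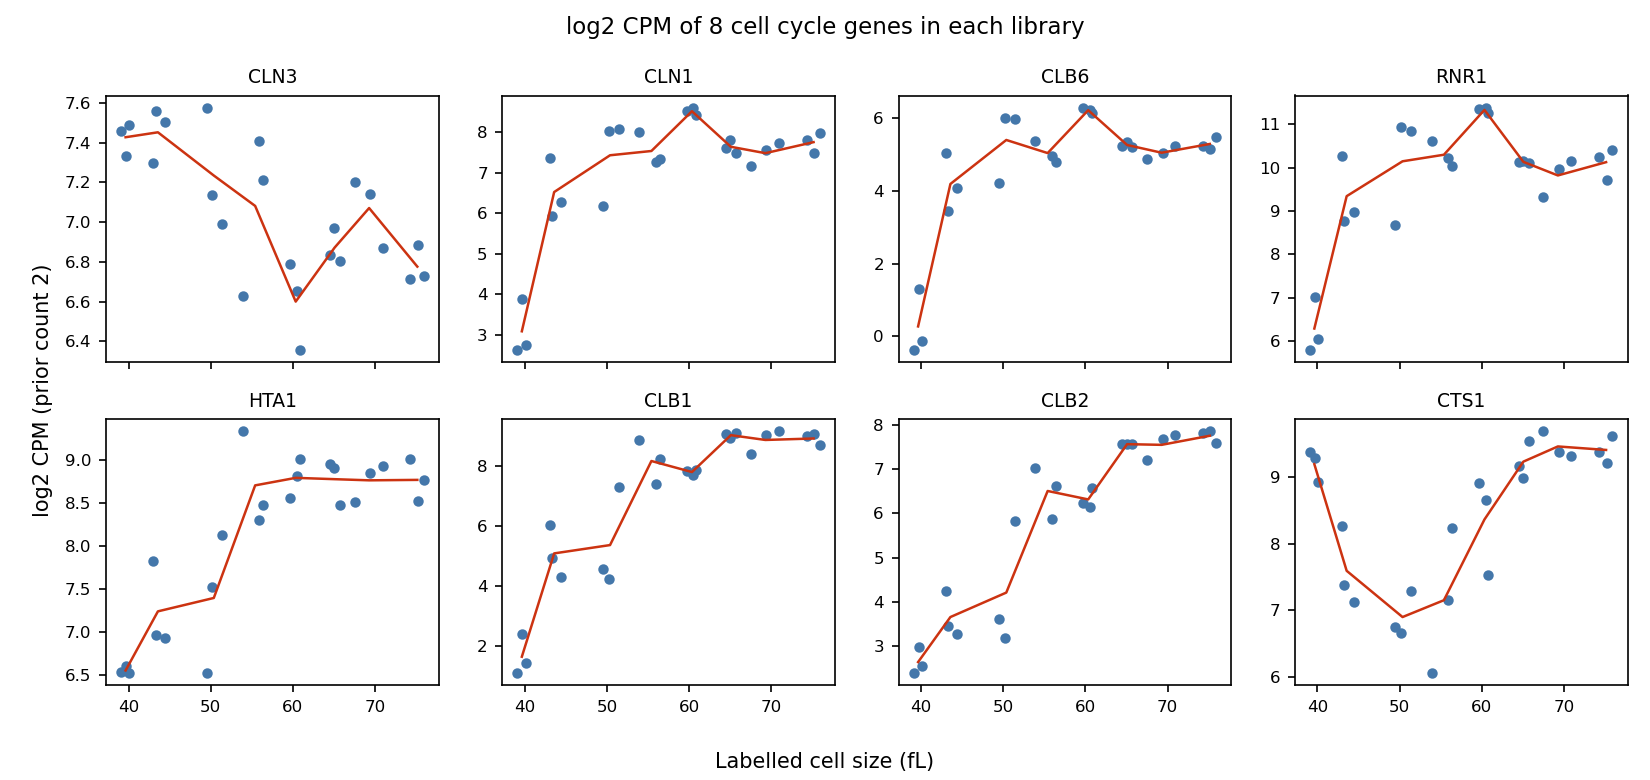
Log2 CPM (prior count 2, y axis) of 8 cell cycle genes against labelled cell size in fL (x axis), where blue points are single libraries and red lines join the means of the 8 size groups. CLN1 rises from 9.11 CPM at 40 fL to 368 CPM at 60 fL, CLB1 goes on to 488 CPM at 75 fL, CLN3 falls from 172 to 110 CPM, and CTS1 dips to 121 CPM at 50 fL.

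Cell cycle lists other than the Mcm1 targets moved up between 40 and 75 fL. Counts of list members are given over all genes tested, and the count adjusted over the list alone was the same unless it is given. All 29 tested G1/S members rose, with a median of 2.41 (camera adjusted p = 6.23e-14, adjusted p = 0.332 with an estimated correlation). Of 43 replication genes 36 rose and 3 fell, with RNR1, a subunit of ribonucleotide reductase, up by 3.77 ± 0.50 and the repair gene RAD54 down by 0.76 ± 0.09 beside RFC4 and EXO1 (median 1.48, adjusted p = 2.65e-08, adjusted p = 0.53 with an estimated correlation). All 9 histone genes rose, with a median of 2.95 (adjusted p = 4.64e-06, adjusted p = 0.332 with an estimated correlation). Of the words of the histone genes HHF1 and HHF2, 40.8% are repeated in the genome, so their separate values are uncertain. Of 35 spindle and kinetochore genes 32 rose and 1, ASK1, fell, with NUF2 up by 2.26 ± 0.23 and SPC42 by 1.48 ± 0.18 (median 1.29, adjusted p = 2.3e-09, adjusted p = 0.332 with an estimated correlation). All 26 members of the CLB2 cluster rose, with a median of 3.29 (adjusted p = 1.22e-15, adjusted p = 0.332 with an estimated correlation). Of 9 Mcm1 targets and MCM genes 4 rose (SWI4, CDC6, MCM4, MCM7) and 2 fell (CLN3, MCM3), and the list did not pass (median 0.07, adjusted p = 0.485). Across the 34 lists camera called 20 between 40 and 75 fL, 13 up and 7 down. With an estimated correlation the haploid-specific list was the single one still called, here and between 40 and 50 fL. Counting the real one, 7 of 10 splits of the 6 libraries of 40 and 75 fL called as many lists or more.

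Ribosome genes split by function between 40 and 75 fL. Of 137 cytosolic ribosomal protein genes 135 rose and none fell, with a median of 1.07 and RPS22A up by 1.44 ± 0.14 (camera adjusted p = 9.79e-33, adjusted p = 0.332 with an estimated correlation). All 107 ribosome biogenesis genes fell, with a median of -1.32, among them ESF2 by -1.47 ± 0.32 (adjusted p = 1.22e-15, adjusted p = 0.547 with an estimated correlation). Of 19 subunits of RNA polymerases I and III 16 fell, or 18 adjusted over the list alone, with RPA49 down by 1.16 ± 0.29 (median -0.85, adjusted p = 0.000165, adjusted p = 0.561 with an estimated correlation). Of 79 small nucleolar RNAs 4 rose and 30 fell, or 4 and 28 adjusted over the list alone (median -0.29, adjusted p = 0.00307, adjusted p = 0.561 with an estimated correlation). The call ends without the 5 libraries that stood apart (adjusted p = 0.0921), and the median is -0.17 without 40 fL replicate 1. Among these snR48 fell by 1.84 ± 0.29, whereas snR18 lies within another gene, EFB1, and its value is uncertain. The 4 that rose were snR30, snR86 and the spliceosomal RNAs snR6 and snR19. Of 31 proteasome genes 17 fell and none rose (median -0.39, adjusted p = 0.000268, adjusted p = 0.582 with an estimated correlation).

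Lists of glycolysis, the TCA cycle and oxidative phosphorylation were higher at 75 than at 40 fL, and the other lists given here did not pass. Of 20 glycolysis and fermentation genes 17 rose and none fell, with a median of 1.65 (camera adjusted p = 7.09e-07, adjusted p = 0.332 with an estimated correlation). PDC1, the main pyruvate decarboxylase (YLR044C, chromosome XII, 232390 to 234081), rose by 2.86 ± 0.25 and CDC19, a pyruvate kinase, by 1.91 ± 0.20. Of 14 TCA cycle genes 12 rose, with the aconitase gene ACO1 up by 1.58 ± 0.35 (median 1.01, adjusted p = 0.0031, adjusted p = 0.561 with an estimated correlation). Of 31 nuclear genes of oxidative phosphorylation 23 rose, or 24 adjusted over the list alone, with COR1 up by 1.27 ± 0.26 (median 0.73, adjusted p = 0.000168, adjusted p = 0.568 with an estimated correlation). Among 8 mitochondrially encoded genes 4 rose (COX1, COB, ATP8, OLI1), or 6 adjusted over the list alone, but the list did not pass (median 0.50, adjusted p = 0.106). Its member COX1 overlaps the genes in its introns, and its rise of 0.33 ± 0.12 turns to -0.11 with deposited TPM. Without 75 fL replicate 2 the calls of COX1, COB and OLI1 end (adjusted p = 0.0908, 0.0687 and 0.0507). The COX1 call also ends without 40 fL replicate 1 or 3 or 75 fL replicate 1 (0.0966, 0.0524, 0.0806), and the COB call without 40 fL replicate 1 (0.0517). The list passes without 75 fL replicate 3 (0.0377). Of 17 trehalose and glycogen genes 4 rose (GSY1, GLG2, PGM1, UGP1) and 1, NTH1, fell (median 0.29, adjusted p = 0.627), and of 13 hexose transporter genes 1 rose, HXT4 by 1.52 ± 0.33, and 1, RGT2, fell, or 1 and none adjusted over the list alone (median 0.08, adjusted p = 0.973). The GSY1 call ends without 75 fL replicate 2 (0.133), and that of NTH1 without 40 fL replicate 1 or 75 fL replicate 1 or 3 (0.0806, 0.109, 0.0537). The hexose transporter list had a median, mean and test that differed in sign. Among 16 glucose-repressed and stationary-phase genes 2 rose (ADH2, SNO1) and 6 fell (median -0.43, adjusted p = 0.111, or 0.0378 without 75 fL replicate 2), with PCK1, a gluconeogenesis gene, down by 2.89 ± 0.38.

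Lipid genes went both ways between 40 and 75 fL, and sterol genes were the lipid list that passed. Of 26 ergosterol genes 15 rose and 2, ERG7 and IDI1, fell, with a median of 0.54 (camera adjusted p = 0.00272, adjusted p = 0.561 with an estimated correlation). ERG11 went from 831 ± 105 to 1392 ± 119 CPM, a rise of 0.74 ± 0.19 that did not pass with deposited TPM, and HMG1, of the committed step, had a difference of -0.02 ± 0.13 that did not pass. Of 16 fatty acid genes 10 rose and 6 fell (median 0.31, adjusted p = 0.349). IFA38, of fatty acid elongation, rose by 1.54 ± 0.18, and OLE1, the fatty acid desaturase (YGL055W, chromosome VII, 398628 to 400160), fell by 1.81 ± 0.42. The fatty acid synthase genes FAS1 and FAS2 fell by 0.54 ± 0.20 and 0.62 ± 0.26 and the carboxylase gene ACC1 by 0.56 ± 0.21, and each call ends when any of several single libraries is left out. Without 40 fL replicate 2, 40 fL replicate 3, 75 fL replicate 2 or 75 fL replicate 3 the adjusted p was 0.0958, 0.0618, 0.0598 or 0.0655 for FAS1. It was 0.129, 0.0900, 0.0512 or 0.108 for FAS2 and 0.0813, 0.0583, 0.0722 or 0.0631 for ACC1, and without 75 fL replicate 1 it was 0.0568 for FAS1 and 0.106 for FAS2. Of 27 phospholipid genes 7 rose and 15 fell (median -0.30, adjusted p = 0.106), with INO1, of inositol synthesis (YJL153C, chromosome X, 134332 to 135933), down by 2.59 ± 0.32, CHO1 by 1.53 ± 0.29 and OPI3 by 1.21 ± 0.19. Of 23 sphingolipid genes 11 rose and 3, LCB4, IPT1 and ORM2, fell (median 0.21, adjusted p = 0.106), and LCB1 had a difference of 0.07 ± 0.08 that did not pass. Among 10 storage lipid genes 4 rose (ARE1, LRO1, TGL1, TGL5) and 4 fell (ARE2, TGL3, TGL4, YEH1), the sterol ester hydrolase gene YEH1 by 0.99 ± 0.17 (adjusted p = 0.684), and the median, mean and test of that list differed in sign.

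Of the remaining lists, cell wall and purine genes moved up, and iron, haploid-specific and meiosis genes moved down. Among 29 cell wall genes 20 rose and 3, TIP1, GSC2 and PIR3, fell, or 21 and 4 adjusted over the list alone, with CIS3 up by 4.15 ± 0.38 (median 1.34, camera adjusted p = 2.54e-05, adjusted p = 0.332 with an estimated correlation). Of 18 purine and one-carbon genes 14 rose and 1, IMD2, fell, with GCV1, of glycine cleavage (YDR019C, chromosome IV, 484163 to 485365), up by 2.29 ± 0.24 and SHM2 by 2.24 ± 0.30 (median 1.18, adjusted p = 0.000234, adjusted p = 0.472 with an estimated correlation). Of 15 iron regulon genes 9 fell, or 10 adjusted over the list alone, the siderophore transporter gene SIT1 by 1.92 ± 0.26 (median -0.55, adjusted p = 0.0017, adjusted p = 0.332 with an estimated correlation). Of 18 haploid-specific and mating genes, which a diploid represses, 14 fell and 1 rose, FAR1, which encodes an inhibitor of G1 cyclin kinases, or 14 and 2 adjusted over the list alone (median -1.25, adjusted p = 8.54e-05, adjusted p = 0.0113 with an estimated correlation). Levels were low, as for FUS3, a mating kinase gene, which fell from 10.1 ± 1.10 to 1.39 ± 0.268 CPM, and 4 of the 14 lost more than 16.5 CPM per kb, a bound set by the 500 weakest genes. Of 17 meiosis and sporulation genes 8 fell and 1, SPS4, rose (median -0.43, adjusted p = 0.0214, adjusted p = 0.332 with an estimated correlation), a call that ends with library totals, with TPM plus 1 and without the 5 libraries that stood apart (adjusted p = 0.0875). Lists that did not pass were environmental stress (5 rose and 6 fell of 30, or 3 and 5 adjusted over the list alone, adjusted p = 0.529) and chaperones (6 rose and 1, YDJ1, fell of 19, adjusted p = 0.146). The chaperone list passes with TPM plus 1 (0.0405) and without the 5 libraries that stood apart (0.0338). The amino acid synthesis list (15 and 9 of 37, adjusted p = 0.702) had a median, mean and test that differed in sign. Sulfur and methionine genes (6 and 4 of 22, adjusted p = 0.702) and the phosphate regulon (0 rose and 3, PHO8, PHO89 and PHM8, fell of 16, or 0 and 2 adjusted over the list alone, adjusted p = 0.525) did not pass, and the PHO89 call ends without 75 fL replicate 3 (0.0813).

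From 40 to 50 fL, G1/S genes rose and ribosome biogenesis genes fell. CLB6, an S-phase cyclin gene (YGR109C, chromosome VII, 705359 to 706501), rose from 1.28 ± 0.95 to 48.5 ± 25.8 CPM (n = 3 each), by 5.19 ± 0.50 on the log2 scale (SE, edgeR adjusted p = 3.54e-06). PCL1, another G1 cyclin gene (YNL289W, chromosome XIV, 87897 to 88736), rose by 5.08 ± 0.54, the cohesin gene MCD1 (YDL003W, chromosome IV, 444683 to 446383) by 4.68 ± 0.55, TOS4 by 4.61 ± 0.56 and the repressor gene YOX1 by 4.54 ± 0.49. CIT2 fell by 3.24 ± 0.31, ARG1 by 3.04 ± 0.56, GAP1 by 2.59 ± 0.28 and DIP5, an amino acid permease gene (YPL265W, chromosome XVI, 41043 to 42869), by 2.59 ± 0.41. DSE2, a cell separation gene (YHR143W, chromosome VIII, 385510 to 386487), fell from 357 ± 62.2 to 47.2 ± 5.51 CPM and the chitinase gene CTS1 (YLR286C, chromosome XII, 708448 to 710136) from 589 ± 91.6 to 121 ± 30.1 CPM. WHI5 rose by 0.86 ± 0.21 in this interval, while CLN3 had a difference of -0.17 ± 0.17 that did not pass (adjusted p = 0.397). BCK2 had a difference of 0.17 ± 0.07 that turns to -0.07 with library totals. Without 50 fL replicate 2 ARG1 stood at -4.68. In edgeR 3653 of 6402 genes passed, 2101 up and 1552 down, of which 625 and 491 changed at least 2-fold. The split was 1219 up and 2518 down with library totals, 1743 and 1956 with upper quartile factors, and 884 and 3090 with deposited TPM (plus 1, limma), where library totals moved the median of all genes from 0.05 to -0.19.

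Lists called between 40 and 50 fL numbered 22 of 34 in camera, 14 up and 8 down. Counting the real one, 2 of 10 splits of the 6 libraries called as many lists or more. All 29 G1/S genes rose (median 2.28, adjusted p = 1.44e-12) and 40 of 43 replication genes (median 1.85, adjusted p = 2.71e-13). So did 8 of 9 histone genes (median 1.68, adjusted p = 0.00194) and 21 of 26 CLB2 cluster genes (median 1.04, adjusted p = 0.000863). Each of these 4 lists had adjusted p = 0.545 with an estimated correlation. The CLB2 cluster median is 0.48 without 50 fL replicate 1. Without that library the edgeR calls of HTA1, HTB1 and HHF1 end (adjusted p = 0.164, 0.0742 and 0.0854). Those of CLB2, CLB4, SPO12 and SWI5 end too (0.0587, 0.0757, 0.115 and 0.846), while CLB1, CHS2 and CDC5 still pass. Histone means of 50 fL replicates 1, 2 and 3 stood at 2.71, 0.81 and 1.94 relative to 40 fL. Of 35 spindle genes 23 rose and 1, ASK1, fell (median 0.81, adjusted p = 0.000189, adjusted p = 0.545 with an estimated correlation). Of 137 ribosomal protein genes 130 rose (median 0.67, adjusted p = 4.07e-19), while 106 of 107 ribosome biogenesis genes fell, or 107 adjusted over the list alone (median -1.18, adjusted p = 1.31e-21). All 19 subunits of RNA polymerases I and III fell (adjusted p = 2.43e-07). Each of these 3 lists, too, had adjusted p = 0.545 with an estimated correlation. The ribosome biogenesis median is -1.90 without 50 fL replicate 2. In glycolysis 18 of 20 genes rose, with PDC1 up by 2.30 ± 0.24 (median 1.67, adjusted p = 1.42e-07), and in the TCA cycle 11 of 14, or 12 adjusted over the list alone (median 1.04, adjusted p = 0.000821), both with adjusted p = 0.545 with an estimated correlation. Oxidative phosphorylation had 22 rises of 31 (median 0.69, adjusted p = 0.00034, adjusted p = 0.57 with an estimated correlation) and trehalose and glycogen 8 of 17 (median 0.79, adjusted p = 0.0248, adjusted p = 0.577 with an estimated correlation).

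Stress genes were up in the same interval. Of 30 environmental stress genes 25 rose, or 26 adjusted over the list alone (median 2.00, camera adjusted p = 1.39e-05), and of 19 chaperone genes 16 rose (median 1.24, adjusted p = 5.67e-05), both with adjusted p = 0.545 with an estimated correlation. GRE1, a stress-induced gene, rose by 4.08 ± 0.63, GND2 by 3.82 ± 0.54 and the hexose transporter gene HXT5 by 2.75 ± 0.53. Ergosterol genes (21 rose and 1, IDI1, fell of 26, median 0.55, adjusted p = 0.000203) and cell wall genes (19 rose and 1, TIP1, fell of 29, median 0.75, adjusted p = 0.00168) moved up, both with adjusted p = 0.545 with an estimated correlation. Iron genes moved down, 10 of 15 falling, or 11 adjusted over the list alone (median -0.59, adjusted p = 3.88e-05, adjusted p = 0.172 with an estimated correlation). Haploid-specific genes moved down too, 14 of 18 falling and 2, FAR1 and RME1, rising (median -0.79, adjusted p = 9.05e-05, adjusted p = 0.0117 with an estimated correlation). Amino acid synthesis had 8 rises and 16 falls of 37, or 8 and 17 adjusted over the list alone (median -0.22, adjusted p = 0.0248, adjusted p = 0.545 with an estimated correlation), a call that ends without 40 fL replicate 2 (0.0538) or 50 fL replicate 2 (0.0655). Meiosis genes (3 rose, IME1, REC8 and SPS4, and 6 fell of 17, median -0.25, adjusted p = 0.0248, adjusted p = 0.545 with an estimated correlation) and small nucleolar RNAs (7 and 25 of 79, or 6 and 23 adjusted over the list alone, median -0.17, adjusted p = 0.0248, adjusted p = 0.577 with an estimated correlation) moved down. Without the 5 libraries that stood apart the amino acid, meiosis and small nucleolar calls end (adjusted p = 0.0534, 0.138 and 0.207). The meiosis and small nucleolar calls end with library totals, the first also with TPM plus 1 (0.0682) and without 50 fL replicate 2 (0.0634) and the second without 40 fL replicate 1 (0.171). The small nucleolar median is -0.27 without 50 fL replicate 2 and -0.10 without 50 fL replicate 3, and the cell wall median 0.50 without 50 fL replicate 1. The SPS4 call ends without 50 fL replicate 1 (0.253) and the TIP1 call without 50 fL replicate 1 (0.0649) or 3 (0.0710).

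From 50 to 60 fL, THI4, HXK2 and CLB2 were among the genes that rose. THI4 rose from 11.3 ± 9.08 to 361 ± 183 CPM (n = 3 each), by 4.99 ± 0.76 on the log2 scale (SE, edgeR adjusted p = 0.0066), and THI22 (YPR121W, chromosome XVI, 778583 to 780301) by 2.97 ± 0.58. HXK2, the main hexokinase (YGL253W, chromosome VII, 23935 to 25395), rose from 270 ± 63.7 to 546 ± 48.5 CPM. CLB2 rose by 1.62 ± 0.47, CDC5 by 1.37 ± 0.34, HTA1 by 1.27 ± 0.33, the cell separation gene EGT2 by 1.95 ± 0.58, DSE2 by 1.61 ± 0.38 and CTS1 by 1.55 ± 0.42. CLN3 fell by 0.65 ± 0.17, INO1 by 1.31 ± 0.31, HXT5 by 1.75 ± 0.51, the cell wall gene SPI1 by 1.92 ± 0.56 and DPI8 by 1.64 ± 0.25. Without 50 fL replicate 1 the rises of CLB2, CDC5 and EGT2 were 2.93, 2.08 and 3.09, and without 50 fL replicate 2 INO1 stood at -0.72. In edgeR 646 of 6402 genes passed, 255 up and 391 down (1957 at an unadjusted p under 0.05), of which 61 and 64 changed at least 2-fold. The split was 335 up and 210 down with RLE factors, 222 and 224 with upper quartile factors, 262 and 172 with deposited TPM (plus 1, limma), 309 and 168 with no filter and 620 and 437 in DESeq2. Without 50 fL replicate 2 edgeR called 1 gene, VRL1 (YML002W; 1490 at an unadjusted p under 0.05), so that every other call named here for this interval ends. Without 60 fL replicate 1, 2 or 3 it called 17, 7 or 3 genes, the last being THI4, HXK2 and VRL1, and without 70 fL replicate 1, which is in neither group, 1057.

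Lists called between 50 and 60 fL numbered 15 of 34 in camera, 12 up and 3 down, none of them with an estimated correlation. Counting the real one, 5 of 10 splits of the 6 libraries called as many lists or more. Of 29 G1/S genes 8 rose, or 17 adjusted over the list alone (median 0.80, adjusted p = 1.55e-15, adjusted p = 0.301 with an estimated correlation). Of 26 CLB2 cluster genes 17 rose, or 23 adjusted over the list alone (median 1.06, adjusted p = 9.62e-18). Of 35 spindle genes 15 rose, or 25 adjusted over the list alone (median 0.55, adjusted p = 2.4e-15). Of 9 histone genes 7 rose, or 9 adjusted over the list alone (median 1.30, adjusted p = 2.35e-09). Each of these 3 lists had adjusted p = 0.278 with an estimated correlation. Among 43 replication genes 1, RFC3, rose, or 0 adjusted over the list alone (median 0.52, adjusted p = 8.44e-13, adjusted p = 0.384 with an estimated correlation). Of 137 ribosomal protein genes 2, RPS11A and RPS26B, rose, or 0 adjusted over the list alone (median 0.22, adjusted p = 1.55e-15, adjusted p = 0.564 with an estimated correlation). Cell wall genes had 9 rises of 29, or 12 and 3 falls adjusted over the list alone (median 0.45, adjusted p = 2.72e-06, adjusted p = 0.278 with an estimated correlation). Without 50 fL replicate 2 the medians of the G1/S, replication, ribosomal protein and cell wall lists are 0.46, 0.21, 0.13 and 0.28. The replication median is 0.78 without 50 fL replicate 3 and the CLB2 cluster median 1.59 without 50 fL replicate 1. Purine genes had 3 rises (SHM2, GCV1, ADE6) and 1 fall (ADE16) of 18, or 8 and 1 adjusted over the list alone (median 0.57, adjusted p = 6.85e-07, adjusted p = 0.301 with an estimated correlation).

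Lipid, stress and proteasome lists moved as well between 50 and 60 fL. Fatty acid genes had 4 rises of 16, those of ELO2, ELO3, PHS1 and ACS2 (median 0.08, camera adjusted p = 0.0149, adjusted p = 0.301 with an estimated correlation) and sphingolipid genes 3 of 23, those of SUR2, LAC1 and ISC1 (median 0.09, adjusted p = 0.0251, adjusted p = 0.278 with an estimated correlation). The fatty acid call ends without 50 fL replicate 1 (0.0852) and the sphingolipid call without 50 fL replicate 3 (0.0771). Without single libraries of 50 fL (replicates 1, 2, 3) or 60 fL (replicates 1, 2, 3) the fatty acid median is 0.00, 0.30, 0.01, 0.16, 0.02 or 0.04, and the sphingolipid median is 0.05 without 60 fL replicate 1. Without 50 fL replicate 1 the amino acid median is 0.11 and the chaperone median -0.28. Amino acid synthesis had 2 rises of 37, HIS1 and TRP3 (median 0.18, adjusted p = 0.000728, adjusted p = 0.516 with an estimated correlation). Environmental stress genes moved down, with 4 falls of 30 (SPI1, YGP1, OM14, HSP31), or 21 adjusted over the list alone (median -1.19, adjusted p = 6.56e-07, adjusted p = 0.564 with an estimated correlation). Chaperones moved down as a list (median -0.45, adjusted p = 0.0251, adjusted p = 0.786 with an estimated correlation). Proteasome genes did so too (median -0.36, adjusted p = 1.79e-06, adjusted p = 0.656 with an estimated correlation). In both lists 0 members passed in edgeR, in DESeq2 and in limma-voom, and 0 adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 5 of 19 chaperone and 20 of 31 proteasome genes. The chaperone call ends without 50 fL replicate 1 (0.247) or 3 (0.0523). Ribosome biogenesis did not pass (median -0.44, adjusted p = 0.148), but it passed downward without 50 fL replicate 1 (8.4e-06) or 3 (0.000486) and upward without 50 fL replicate 2 (1.31e-06). With all libraries it passed downward with RLE factors (0.0244) and with no filter (0.0198), and without the 5 libraries that stood apart it passed upward (1.07e-12). The RNA polymerase I and III list, whose median (-0.17) and test differed in sign (adjusted p = 0.943), passed upward without 50 fL replicate 2 (0.000527) and without the 5 libraries (1.49e-05).

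From 60 to 75 fL, KIN3, MOB1 and GCV1 were among the genes that rose, and THI4 and THI22 among those that fell. KIN3, a mitotic kinase gene (YAR018C, chromosome I, 170396 to 171703), rose from 23.6 ± 2.70 to 76.3 ± 10.8 CPM (n = 3 each), by 1.69 ± 0.27 on the log2 scale (SE, edgeR adjusted p = 0.00192). MOB1, of the mitotic exit network (YIL106W, chromosome IX, 166415 to 167444), rose by 0.91 ± 0.10. MYO1, the myosin of the contractile ring (YHR023W, chromosome VIII, 151666 to 157452), rose by 1.02 ± 0.20, SIC1 by 0.78 ± 0.15 and ASH1, a repressor active in daughter cells, by 1.29 ± 0.25. GCV1 rose by 1.76 ± 0.23, from 84.6 ± 13.2 to 286 ± 65.3 CPM. THI4 fell by 6.43 ± 0.83, from 361 ± 183 to 4.18 ± 0.893 CPM, and THI22 by 3.59 ± 0.60. OPI3, a phospholipid methyltransferase (YJR073C, chromosome X, 572315 to 572935), fell by 1.08 ± 0.19, RAD54 by 0.68 ± 0.09 and the chromatin assembly gene RLF2 (YPR018W, chromosome XVI, 594476 to 596296) by 0.77 ± 0.14. In edgeR 257 of 6402 genes passed, 128 up and 129 down (1153 at an unadjusted p under 0.05), of which 44 and 26 changed at least 2-fold. With deposited TPM (plus 1, limma) 156 of 257 calls were down, with no filter 168 of 270, and in DESeq2 277 of 452. The count was 158, 125 or 80 without 60 fL replicate 1, 2 or 3, 113 or 97 without 75 fL replicate 1 or 2, and 466 without 50 fL replicate 2, which is in neither group.

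Lists called between 60 and 75 fL numbered 12 of 34 in camera, 6 up and 6 down, none of them with an estimated correlation. Counting the real one, 7 of 10 splits of the 6 libraries called as many lists or more. Of 26 CLB2 cluster genes 9 rose, or 19 adjusted over the list alone (median 1.09, adjusted p = 5.65e-12, adjusted p = 0.521 with an estimated correlation). Of 18 purine and one-carbon genes 9 rose, or 14 adjusted over the list alone (median 0.70, adjusted p = 1.03e-10, adjusted p = 0.382 with an estimated correlation). Iron genes had 2 rises of 15, FET3 and ENB1 (median 0.27, adjusted p = 0.0123, adjusted p = 0.521 with an estimated correlation). Of 43 replication genes 10 fell, or 41 adjusted over the list alone (median -0.89, adjusted p = 3.54e-29, adjusted p = 0.382 with an estimated correlation), and of 29 G1/S genes 1, MNN1, fell, or 2 adjusted over the list alone (median -0.75, adjusted p = 1.88e-08, adjusted p = 0.784 with an estimated correlation). The lists that follow were called by camera with 0 members passing in edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 they had 7 of 137 ribosomal protein, 0 of 107 ribosome biogenesis, 12 of 30 environmental stress, 2 of 26 ergosterol, 4 of 19 chaperone and 1 of 31 proteasome genes. In DESeq2 3 stress genes passed and 0 of the other lists, and in limma-voom 0 in any of them. Upward were ribosomal proteins (median 0.17, adjusted p = 7.51e-06) and ribosome biogenesis (median 0.32, adjusted p = 0.00351), each with adjusted p = 0.92 with an estimated correlation. The second of these ends without 75 fL replicate 1 (median 0.19, adjusted p = 0.243). Environmental stress genes moved down (median -0.90, adjusted p = 3.95e-09, adjusted p = 0.726 with an estimated correlation). So did ergosterol (median -0.15, adjusted p = 0.000834), chaperone (median -0.35, adjusted p = 0.00143) and proteasome genes (median -0.09, adjusted p = 0.0351), each with adjusted p = 0.92 with an estimated correlation. The proteasome call ends without 60 fL replicate 1 (0.0575) or 3 (0.0786) or 75 fL replicate 1 (0.105) or 3 (0.0521), with library totals (0.0588) and with TPM plus 1 (0.100).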

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

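The alternative without the 5 libraries that stood apart was chosen after the data were seen. Counts of genes over the 8 sizes, from 40 to 50 fL and from 40 to 75 fL stayed within 1.5 times under all alternatives, with 4437 (spline) to 5445 (without the 5 libraries) of 5096 over the 8 sizes, and leaving out 1 library gave 4664 to 5293, 2612 to 4115 and 3430 to 4075. The 646 genes from 50 to 60 fL became 412 with library totals, 1057 in DESeq2, 415 with TPM plus 0.1, 256 with the 6 libraries only, 7 with a fold threshold of 1.2 and 1786 without the 5 libraries, and 1 to 1057 when 1 library was left out (1 without 50 fL replicate 2). The 257 genes from 60 to 75 fL became 452 in DESeq2, 1129 with the 6 libraries only, 79 with the fold threshold and 1420 without the 5 libraries, and 80 to 466 when 1 library was left out. The cause was not tested, except that a fold threshold asks more of each gene by construction. Called lists numbered 1, 0, 0 and 1 with an estimated correlation (40 to 50, 50 to 60, 60 to 75 and 40 to 75 fL), against 22, 15, 12 and 20, fry, which does not compare a list with other genes, gave 26, 9, 6 and 27, among the last the fatty acid (0.00271), phospholipid (0.00265), sphingolipid (3.03e-06) and storage lipid (0.00265) lists that camera did not call, and leaving out 1 library gave 19 to 24, 15 to 18, 11 to 16 and 20 to 21. No list called with all libraries turned its direction, but ribosome biogenesis from 50 to 60 fL, which was not called, passed in opposite directions without different 50 fL libraries. Named genes that did were BCK2 from 40 to 50 fL (-0.0728 with library totals, -0.21 with TPM plus 1 and -0.21 with TPM plus 0.1), ERG29 in that interval (-0.00151 and -0.00168 with TPM plus 1 and plus 0.1) and COX1 from 40 to 75 fL (-0.11 with either), for which the cause was not tested. Class shares at 75 fL minus those at 40 fL moved with TPM by more than the spread between replicates, to 1.29 percentage points for all other features, the opposite sign to that in counts, -1.35 for small nucleolar RNA, 0.172 for small nuclear and other small structured RNA and -0.126 for tRNA, since TPM weights short features more by construction. No paired analysis was possible because the labels carry no replicate numbers that link libraries of different sizes. Depth limits weakly expressed genes, since 3 counts stand for 0.186 CPM in the smallest library, without a TMM factor.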

Other observations

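The 3 lists of nutrient and oxygen genes described first, and all tests here except the regroupings of libraries, were chosen after the results were seen. Thiamine synthesis and uptake genes were high and low by turns along the series. Their mean stood above that at 40 fL by 1.55 ± 0.12 at 45 fL, 0.57 ± 0.30 at 50 fL, 1.11 ± 0.38 at 55 fL, 2.07 ± 0.49 at 60 fL, 1.67 ± 0.29 at 65 fL, 1.99 ± 0.19 at 70 fL and 0.33 ± 0.07 at 75 fL (log2, SD, n = 3). THI4 stood at 2.59 ± 0.667 CPM at 40 fL, 78.1 ± 30.1 at 45 fL, 11.3 ± 9.08 at 50 fL, 361 ± 183 at 60 fL, 267 ± 86.5 at 70 fL and 4.18 ± 0.893 at 75 fL.

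Genes repressed by good nitrogen sources had lower means at 45 to 75 fL than at 40 fL, and 20 of 22 passed over the 8 sizes in edgeR. Of all tested genes 79.6% passed that test, so such counts alone do not set these lists apart. Their mean lay at -0.74 ± 0.03 at 50 fL, -1.10 ± 0.07 at 65 fL and -0.76 ± 0.11 at 75 fL (log2 relative to 40 fL, SD, n = 3). GAP1 went from 530 ± 63.8 CPM at 40 fL to 26.7 ± 3.06 at 65 fL, and the urea transporter gene DUR3 (YHL016C, chromosome VIII, 72037 to 74244) from 113 ± 24.2 to 16.6 ± 0.433 CPM at 70 fL. Genes of low oxygen were highest at 65 fL, with a mean of 2.30 ± 0.53, and at 75 fL stood at 0.90 ± 0.23, and 11 of 11 passed over the 8 sizes. Among them TIR1 went from 8.22 ± 3.91 CPM at 40 fL to 947 ± 303 at 65 fL, the heme synthesis gene HEM13 (YDR044W, chromosome IV, 546642 to 547628) from 94.2 ± 41.8 to 825 ± 74.6, and ANB1 (YJR047C, chromosome X, 524908 to 525381) from 28.3 ± 6.77 to 220 ± 57.1. The labels give 1 medium for all pools and no culture density or aeration per pool, so these were not tested as causes.

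Of 20 thiamine genes 19 passed over the 8 sizes, where 79.6% of all tested genes did. Reads shared between near-identical copies were weighed first, since THI5 and the SNZ genes have close copies. The 12 thiamine genes with under 20% of their words repeated in the genome had a median change of -1.22 from 60 to 75 fL (log2). None of 10000 random lists of like expression (0 of 10000) had a median as low, the lowest being -0.45, which argues against shared reads as the whole source of this fall. The list was drawn up after THI4 and THI22 were seen to fall, and without these the other 10 had a median of -1.02, where the lowest of 10000 random lists was -0.38. The other 8 genes had a median of -2.13, so part of their change stays open. A difference in thiamine supply between cultures may be a candidate explanation, but it was not tested.

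Some libraries of the same size lay far apart, as 50 fL replicate 2 did. It was nearest to 45 fL replicate 1 (distance 0.288, against a mean of 0.680 to its own size), 55 fL replicate 2 to 60 fL replicate 1 (0.378 against 0.574) and 70 fL replicate 1, labelled 67.5 fL, to 65 fL replicate 2 (0.434 against 0.521). After all libraries were thinned to the lowest total, 5 of 5 still stood apart, which argues against sequencing depth. The distance between libraries of a size had a Spearman rho of 0.389 with the difference of their labelled sizes (24 pairs, permutation p = 0.229), so labelled size stays open. A candidate explanation is that pools of one size were at different points of one expression program, since within sizes ribosome biogenesis and G1/S means deviated in opposite directions across the 24 libraries (Pearson r = -0.727, permutation p = 0.0344, Spearman rho = -0.542, permutation p = 0.0546, 100000 permutations, 1 relation computed). Without 50 fL replicate 2 and 55 fL replicate 2, the farthest from the median, r was -0.559. The deviations were still taken from group means that included both libraries, so this value does not show the relation without them. The pattern had been seen in both libraries before the test. Among the libraries that stood apart, 70 fL replicate 1 did not show it. Its ribosome biogenesis mean (-1.44) and G1/S mean (2.44) both lay below those of its group (-1.34 and 2.71). It differed from its mates in trehalose and glycogen genes (1.48 against 0.51 and 0.10) and proteasome genes (0.32 against -0.37 and -0.46). In the others that stood apart, ribosome biogenesis and G1/S means deviated in opposite directions. This relation thus leaves 70 fL replicate 1 unexplained.

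Haploid-specific genes fell from 40 fL although the strain is diploid. None of 10000 random lists of like expression (0 of 10000) had a median as low as -1.25, the lowest being -1.05, which argues against a general fall of weak genes. Background reads spread over the genome stay open. Of the 14 members that fell, 4 lost more CPM per kb than 16.5, the 95th percentile among the 500 weakest genes (3 of those 500 were tRNA genes). With a bound of 11.8, which left out structural RNA and was chosen after the first was seen, 6 did. The median loss was 8.59. A loss under such high bounds does not show background, and the random lists were not matched for gene length, so neither test decides. Haploid cells in the pools of small cells, which sorting by size would not remove, could also lower both mating types together. Here 5 of 5 a-specific and 3 of 3 alpha-specific members fell, 8 in all, led by MF(ALPHA)1 (YPL187W). That gene has words that are repeated in the genome, within it or outside it. A change in repression would lower both mating types too. Background reads, haploid cells and a biological change cannot be told apart here.

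The 24 libraries were regrouped at random into 8 groups of 3. A count as large as the real 5096 came in 1 of 100 groupings, the real one, and the others gave 913 at most. This argues against chance for the 8 sizes. A share of 1 in 100 is the smallest this test could give, and it does not tell size from culture. For the contrasts the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 3653, 646, 257 and 3919 genes from 40 to 50, 50 to 60, 60 to 75 and 40 to 75 fL, each the largest in 1 of 10, with at most 757, 0, 0 and 0 in the others. For lists 2, 5, 7 and 7 of 10 splits gave as many as the real 22, 15, 12 and 20, with at most 24, 20, 18 and 23 in the others. The number of lists called thus did not set the real groups apart from mixed ones. The sides of a mixed split still held unequal numbers of libraries of each size, so part of the size difference stayed in it. These counts therefore do not show whether the list changes arose by chance.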
